A study of Mus musculus with 6 samples.

How the data were processed

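Single cells from mouse lung were profiled by droplet RNA sequencing with unique molecular identifiers (UMIs, tags that let each captured RNA molecule be counted once). Per the labels, lung cells lacking the epithelial antigen Epcam, the endothelial antigen CD31 and the leukocyte antigen CD45 were sorted from mice that carry a smooth muscle actin GFP reporter (SMA) and a tdTomato (Tm) lineage reporter driven by Cre from the Tbx4 gene. The labels name 6 samples, which are 3 sort gates (SMA+Tm+, SMA−Tm+ and SMA−Tm−) on day 0 and on day 21 after bleomycin, a drug that injures the lung and is used to induce fibrosis. Each gate and day has 1 sample, so the design holds no replicates.

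The deposited count table holds whole UMI counts of 27998 genes in 10410 barcodes, with nothing normalized. Per the submitters' processing notes, STAR 2.5.1 and Cell Ranger 1.3.0 were used with the mm10 mouse genome. How the authors called cells is not given in the sources used here. The authors' normalized table is a signal on a linear scale for the same barcodes: it lists 19562 genes, without the 8436 genes that have no UMI in any barcode, and every barcode sums to 2631.5, the median UMI total. Scaling each barcode's counts to that total gave the deposited signal values with a largest gap of 4.775e-12, so the normalized table adds no information to the counts. It was used only for an alternative clustering and for means over cells.

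Both tables hold the cells of all samples together. Barcodes end in a suffix from 1 to 6, and neither the column names nor the labels used here tie a suffix to a labelled sample. No suffix was given a day or a gate, since that would have meant inferring the condition from order or from the values. The table was therefore treated as 1 pooled sample. The planned comparisons of day 21 with day 0, of SMA+ with SMA− cells and of Tm+ with Tm− cells were not made, and no test and no p-value was computed. Suffixes appear only as parts of the table, each with its own value. Cells of suffixes 1 to 3 held Y-linked transcripts and those of suffixes 4 to 6 held Xist, with few exceptions. The suffixes thus differ in the sex of the mice, and differences between suffixes 1 and 4 can include sex. The comparisons that remained were between cell classes within the pooled table, which answer the part of the design that asks how mesenchymal cells divide into subtypes. Reporter transcripts (GFP, tdTomato and Cre) were not analysed here.

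A barcode was kept at 500 or more genes and at most 10% mitochondrial UMIs, which left 9994 of 10410. There were 318 barcodes under the gene minimum and 105 over the mitochondrial maximum. Scrublet (in scanpy 1.11.5), run for each suffix, called 89 doublets (0.891% of those kept), which were removed. This left 9905 cells with 34100616 UMIs and a median of 2698 UMIs and 1213 genes per cell. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were clustered by the Leiden method at resolution 0.8 on 15 neighbours with seed 0 and no batch correction (scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1).

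Clusters were named from 16 marker lists. These lists, the 23 gene lists, the thresholds of the cell filter and most other settings named below were fixed before the data were examined. In the table were 172 of 175 marker symbols and 368 of 373 gene list symbols. The rules that turn markers into names were written after preliminary clusters had been seen. In the clustering of all cells, a marker passed at 50 CPM and at 4-fold over the lower quartile of clusters, with 10 CPM added to both sides of a fold. A name needed a share of 0.6 of its list and at least 3 markers, or, for immune cells, 5 of 14 markers. Mesenchymal and mesothelial cells were then clustered again without any gene of the 23 lists, which left 1869 of the 2000 variable genes, so no list gene drew these clusters directly. List genes did take part in the first clustering, and some are also markers that gave names. Genes that vary with them may also have been kept, so list results are not independent of the classes. There, a cluster took the name with the most markers among its 50 leading genes, at least 3, unless another name had over 0.75 as many or the leading name was not mesenchymal. Other resolutions and other doublet calls were looked at before these settings were run in full. A rule that set aside cluster M6 was tried and dropped with its results seen both ways.

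For each class, UMIs were summed over its cells and over all other mesenchymal cells (with mesothelial cells) and compared as a ratio of CPM, the counts scaled to a common total. Single ratios have exact conditional binomial intervals, single levels exact Poisson intervals and shares exact Clopper-Pearson intervals, at 95%. Intervals of list medians are the central 95% of medians from repeated Poisson redraws of the counts, with the measured members held fixed. They leave out the choice of members. All these intervals cover counting error only and not variation between mice. A list member was measured at 20 CPM on either side and counted higher or lower at 1.5-fold. The name fibrillar collagens below stands for the list of fibrillar and associated collagens, which also holds Col6a3, Col8a1, Col12a1 and Col14a1. A list's median log2 ratio was set against 10000 random lists of the same size, matched on expression in 20 bins, as a description of this table. A side with under 3 UMIs was put at 3 UMIs for the ratio. For such single genes the text gives the counts and the interval or its limit in place of that ratio. List medians and the counts of members higher or lower do include ratios with a side put at 3 UMIs. Where a class holds few UMIs, this can hide how low a gene is. Class ratios were recomputed within each suffix where the class and the other cells each had at least 40 cells. This left suffixes 1 and 4 for most classes. The minimum of 40 is not counted here among the settings fixed in advance. Pericyte-like cells numbered 42 in suffix 4, just above it, so their values within that suffix depend on this minimum. Gene positions come from GENCODE release M21 (GRCm38, the assembly also called mm10), in which 498 of 498 list and marker genes had coordinates.

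The rule for named genes had been written for the day and gate comparisons. Its parts that need no groups were used: Acta2, Pdgfrb, Pdgfra and Tbx4, 2 to 4 members with the largest and smallest ratios of a list, and the 3 leading genes of each cluster. A lowest member with under 3 UMIs was passed over for the next member, and for some lists only the median is given. Some list members that the rule names are not reported here.

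The steps were tested on data simulated with counting error only, which is the error that the intervals assume. For the ductal myofibroblast-like class against other cells, 96.0% of 6308 simulated intervals held the true ratio, and of 100 genes changed by a log2 of 1 and 100 changed by a log2 of 2, 100% and 100% were recovered. These genes stood at 20 CPM or more in the other cells, and the class held 1547144 UMIs. Recovery of genes with few UMIs, as in smaller classes, was not simulated. Of 449 unchanged simulated lists, 4.90% lay outside the central range of the random lists. Of 960 simulated cells of 4 classes, 98.5% fell in a cluster with their class name. Those cells were drawn from the summed profiles of the 4 named fibroblast and mural classes, without the unnamed clusters. Cells of a class differed only by depth and counting error, so this rate does not show how stable the names are in the real cells.

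The other settings fixed in advance were all barcodes without a filter, a stricter filter, keeping doublets, resolutions 0.4 and 1.5, fewer components, clustering on the authors' normalized table, thinning every cell to 1500 UMIs, means over cells, other list minimums, and scaling by edgeR's TMM factors (edgeR 4.0.16) or DESeq2's size factors (DESeq2 1.42.0, in R 4.3.3). TMM factors lowered all log2 ratios of the pericyte-like class by a shift of -0.36 and DESeq2 factors by -0.35, and they shifted the Col14a1 class by 0.11 and 0.12. Settings added after seeing the data were leaving out suffix 1 or suffix 4, centring genes per suffix, another seed, giving the other classes equal weight, and leaving out the unnamed clusters M6 and M10. Figures were drawn with matplotlib 3.10.9.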

Results

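The data are UMI counts of single cells from the lungs of SMA reporter and Tbx4 lineage reporter mice, sorted without epithelial, endothelial and leukocyte antigens, from normal lung (day 0) and from lung on day 21 after bleomycin. The table pools 6 samples, 1 per gate and day, whose cells carry barcode suffixes 1 to 6 that are not tied to a labelled sample. Suffixes 1 to 6 held 1406, 2197, 1439, 3059, 1602 and 707 barcodes with 3326922, 4833588, 4831160, 12427810, 7065269 and 2778071 UMIs. After filtering they held 1320, 1980, 1372, 2976, 1574 and 683 cells, and the median UMI count per cell was 1886, 1783.5, 2383, 3632.5, 3536.5 and 2816. The study asks how lung mesenchymal cells divide into subtypes in the normal and the fibrotic stage. The values below describe the pooled cells, with no replicate check and no comparison of days or gates.

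Immune-like cells were the largest compartment of the table, although the labels describe a sort against CD45. Of 9905 cells, 5914 were immune-like (59.7%, 95% interval 58.7 to 60.7) and 2949 were mesenchymal (29.8%, 28.9 to 30.7). Endothelial-like cells made up 6.61%, epithelial-like cells 1.40%, mesothelial-like cells 1.1%, proliferating cells 0.989% and lymphatic endothelial-like cells 0.414%. The largest immune clusters were led by the alveolar macrophage genes Chil3 and Ear1 (1116 cells), by the B cell gene Fcer2a (997 cells) and by the T cell gene Cd8b1 (662 cells), and a cluster of 741 cells was led by Vpreb3. Ptprc, which encodes CD45, stood at 498 CPM in immune-like and 7.31 CPM in mesenchymal cells. Pecam1, which encodes CD31, stood at 996 CPM in endothelial-like and 9.42 CPM in mesenchymal cells, and Epcam at 137 CPM in epithelial-like and 1.66 CPM in mesenchymal cells.

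The share of mesenchymal cells differed widely between suffixes. In suffixes 1 to 6 it was 55.7%, 3.69%, 3.35%, 67.6%, 2.86% and 5.71%, and the immune-like share was 33.0%, 81.5%, 86.4%, 25.9%, 85.8% and 81.8%, as the plot of compartments by suffix shows. Acta2, the smooth muscle actin gene, stood at 75.2, 2.18, 2.17, 94.1, 0.719 and 6.40 CPM over all cells of these suffixes. Without suffix 4 the mesenchymal share of the table was 13.4%. The sort gates and the calling of cells can set such shares.

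**Figure D1:**
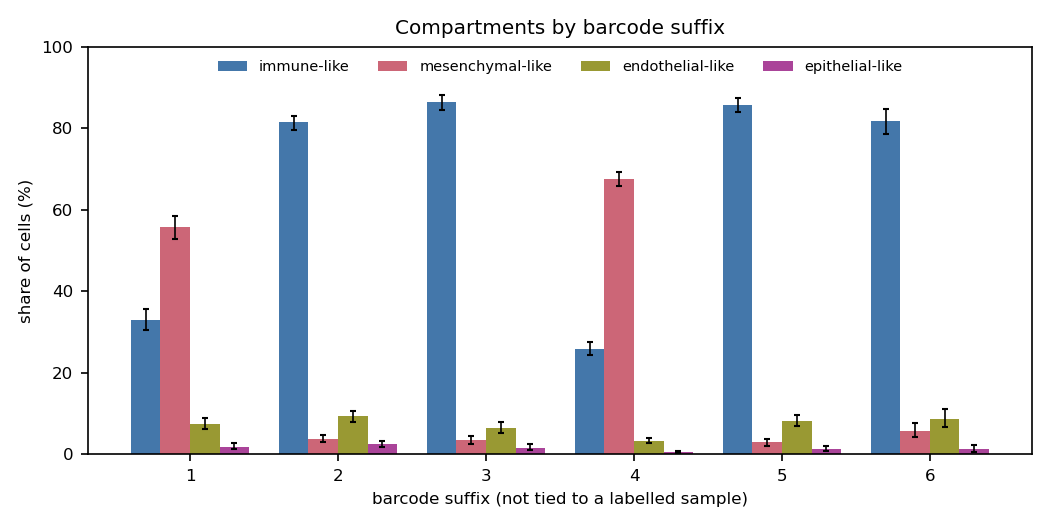
Share of cells (%, from 0 to 100) in 4 compartments for each barcode suffix, with bars for shares and lines for exact 95% binomial intervals. Mesenchymal shares were 55.7% and 67.6% in suffixes 1 and 4 and at most 5.71% in the other suffixes.

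Clustering 3058 mesenchymal and mesothelial cells gave 10 clusters, of which 5 took a name. Cluster M1 was ductal myofibroblast-like (659 cells, 21.6%, 20.1 to 23.1), led by Hhip, Aspn and P2ry14. Clusters M2 and M3 were like the matrix fibroblasts known by the collagen genes Col13a1 (657 cells, 21.5%, 20.04 to 22.98; led by Slc7a10, Colq and Wnt2) and Col14a1 (538 cells, 17.6%, 16.3 to 19.0; led by Pi16, Scara5 and Ly6c1). Mesothelial-like cells (82, led by Cxcl13, Wt1 and Upk3b) were 2.68%. Pericyte-like cells (60, led by Higd1b, Cox4i2 and Spp1) were 1.96% (1.5 to 2.52), or 1.14% under the stricter filter of 1000 genes and 5% mitochondrial UMIs. The largest unnamed cluster, M4 (529 cells, 17.3%, led by Cdh22, Kcnk2 and Bcas3), had 2 Col13a1 class markers among its leading genes, under the minimum of 3. Other unnamed clusters were M5 (248 cells, led by Rbp4, Adam23 and Aox3), M6 (168, led by Scgb1a1, Scgb3a1 and Scgb3a2), M7 (83, led by Adh7, Bmp7 and Aqp1) and M10 (34, led by Slpi, Lgals2 and Aqp1). M5 and M6 recurred poorly: over 4 other seeds the best overlap (Jaccard index) was 0.365 to 0.961 (median 0.481) for M5 and 0.192 to 0.927 (median 0.209) for M6. The 4 named fibroblast and mural classes were found in all 12 alternative clusterings. The Col13a1 share moved with the settings and was 13.5% without suffix 4. With only the seed changed it was 32.9%, and the cluster that overlapped M4 best (Jaccard index 0.586) took the Col13a1 name. The same happened with doublets kept (30.9%), at resolution 1.5 (30.8%), with fewer components (31.6%) and after centring genes per suffix (33.7%), with overlaps of 0.464, 0.458, 0.394 and 0.490. In suffixes 1 and 4, which held 752 and 2071 of the cells, ductal myofibroblast-like cells were 35.5% and 18.5% and Col13a1-like cells 7.58% and 25.01%.

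Transcripts of the endogenous genes Acta2, Pdgfrb, Pdgfra and Tbx4 were unevenly spread over these classes. Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590, minus strand, GRCm38) stood at 2891 CPM (2577 to 3232) in pericyte-like and 516 CPM (481 to 553) in ductal myofibroblast-like cells (306 CPM, 257 to 361, in suffix 1 and 609 CPM, 563 to 657, in suffix 4), against 19.6 CPM in Col13a1-like, 20.2 CPM in Col14a1-like and 1.27 CPM in immune-like cells. Pdgfrb (ENSMUSG00000024620, chromosome 18, 61045150 to 61085061), the PDGF receptor of mural cells, was at 1665 CPM (1430 to 1929) in pericyte-like cells and at 99.5, 48.1 and 147 CPM in the ductal, Col13a1 and Col14a1 classes. Pdgfra (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215), the PDGF receptor of fibroblasts, was at 1323 CPM (1271 to 1378) in Col13a1-like and 377 CPM in Col14a1-like cells. It stood at 14.2 CPM in ductal myofibroblast-like cells, although it is on their own marker list, and had 0 UMIs in pericyte-like cells, a count that allows up to 34.5 CPM. Tbx4 (ENSMUSG00000000094, chromosome 11, 85886422 to 85916097), a transcription factor gene of lung mesenchyme and the driver of the lineage reporter, was at 99.5, 91.1 and 140 CPM in ductal, Col13a1-like and pericyte-like cells and at 14.6 CPM in Col14a1-like cells.

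**Figure D2:**
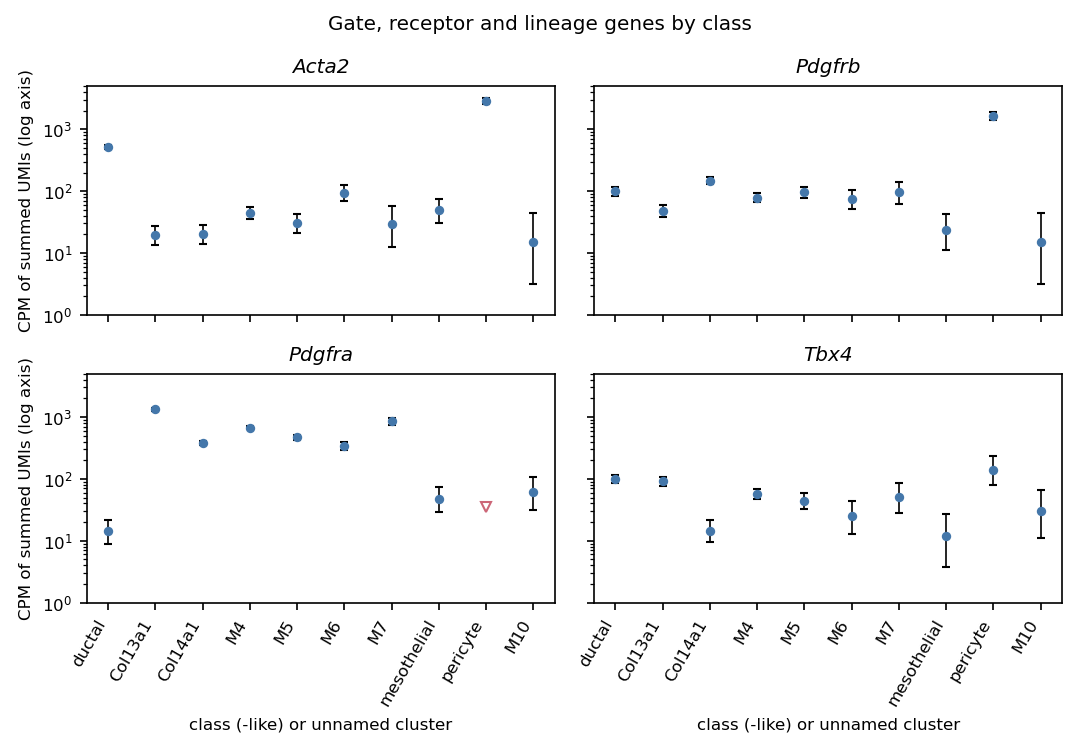
CPM of summed UMIs (log axis) of Acta2, Pdgfrb, Pdgfra and Tbx4 in each class or unnamed cluster, with points for levels, lines for exact 95% Poisson intervals and an open triangle for the upper limit at 0 UMIs. Acta2 and Pdgfrb were highest in pericyte-like cells (2891 and 1665 CPM) and Pdgfra in Col13a1-like cells (1323 CPM).

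Ductal myofibroblast-like cells, a type described around the alveolar duct mouths, combined contractile genes with low complement, chemokine and retinoid genes. Compared with other mesenchymal cells, 9 of 13 measured contractile genes were higher and 1 was lower, with a median log2 ratio of 1.78 (1.66 to 1.95, percentile 100 of random lists). Myocd, which encodes the master coactivator of smooth muscle genes, was 32.3-fold higher (log2 5.01, 3.64 to 6.73), Lmod1 8.19-fold higher and Acta2 7.22-fold higher (log2 2.85, 2.70 to 3.01; 1.68 and 3.06 within suffixes 1 and 4), while Smtn was 1.93-fold lower. All 9 measured complement genes were lower (median -3.61, -3.90 to -3.25), C7 by 28.2-fold and C1s1 by 17.7-fold, and so were 10 of 11 chemokines and cytokines (-2.44, -3.05 to -1.92), with Ccl11 48.4-fold and Cxcl14 74.3-fold lower. Retinoid handling genes were lower in 6 of 7 (-2.40), with the alcohol dehydrogenase gene Adh1 14.1-fold lower.

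The medians of the matrix lists in this class were negative, with members on both sides. Basement membrane genes were lower in 10 of 12 (median -1.32, -1.52 to -1.14), with the laminin gene Lamb1 49.4-fold and Npnt 73.9-fold lower, but Lama4 was 1.83-fold higher. Of 19 provisional matrix genes 11 were lower (-0.85, -1.15 to -0.73), including the fibronectin gene Fn1 (33.9-fold) and, from 3 UMIs in the class, Fbln2 (31.8-fold, log2 -4.99, -7.27 to -3.43), whereas Lum and Thbs2 were 10.8-fold and 6.19-fold higher. Fibrillar and associated collagens had a median of -0.40 (-0.53 to -0.29), with Col1a2 3.20-fold lower and Col12a1 7.71-fold higher. Collagen processing genes had a median of -0.74, with Lox 17.2-fold lower and the prolyl hydroxylase gene P4ha3 79.5-fold higher. Matrix proteases and inhibitors were lower in 10 of 13 (-1.27; Mmp3 17.8-fold lower, Adamts1 2.88-fold higher) and lipid handling genes in 6 of 9 (-1.12). The TGF-beta response list had a median of 0.35 (0.12 to 0.48), with Inhba 3.60-fold higher and Ltbp2 3.78-fold lower. Immediate early genes, which tissue dissociation can induce, were higher in 10 of 17 (0.72, 0.67 to 0.99), led by Ier3 (4.20-fold) and Socs3 (3.79-fold).

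Among signalling genes, the Wnt inhibitor gene Wif1 was 112-fold higher (log2 6.81, 5.40 to 8.72) and Wnt5a 4.82-fold higher, while Wnt4 was 14.4-fold lower. Fgf18 was 20.1-fold higher, and Pdgfra was 45.9-fold and Figf 29.8-fold lower; Wnt5a, Fgf18 and Pdgfra are also on the marker list of this class. Members of these lists went both ways, with medians of -0.23 for the Wnt pathway and -0.11 for growth factors. The hedgehog list had a median of -0.80, although Hhip, a hedgehog antagonist gene and a leading gene of the cluster, was 73.6-fold higher. The tendon factor gene Scx was 78.7-fold and Tbx3 3.58-fold higher, and Tcf21 and Meox2 were 39.5-fold and 39.9-fold lower, with a transcription factor median of 0.12. Smaller medians were 0.37 for hypoxia and glycolysis, 0.20 for proliferation, -0.34 for secretory genes, -0.32 for mitochondrially encoded genes, -0.79 for interferon response, -0.99 for antigen presentation and 0.55 for sex-linked genes. The sex-linked median of a class can reflect its mix of suffixes, since suffix 1 held Y-linked transcripts and suffix 4 held Xist. Within suffixes 1 and 4 the contractile median was 1.68 and 1.81 and the complement median -3.35 and -3.20, but the fibrillar collagen median was -0.02 (-0.30 to 0.19) and -0.53, the hypoxia median was 0.05 and 0.51, and the Wnt, growth factor and sex-linked medians changed sign in a suffix. With the other classes weighted equally, which gives pericyte-like cells more weight, the contractile median was 0.51 and the Acta2 log2 ratio 0.54.

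Col13a1-like fibroblasts were higher for most lipid handling genes and lower for most chemokines. Only the share and the Pdgfra ratio of this class were recomputed under the other settings, not its list medians. Its reference cells include M4, whose best match took the Col13a1 name under some of those settings. Of 12 basement membrane genes 5 were higher and 1 lower (median 0.41, 0.33 to 0.52, percentile 99.1), with Npnt, a marker of the class, 9.51-fold and Col18a1 2.59-fold higher and Col15a1 12.3-fold lower. Lipid handling genes were higher in 7 of 10 (0.93, 0.67 to 1.03, percentile 100): Angptl4 by 3.90-fold and the lipid droplet gene Plin2 by 3.46-fold, while the lipoprotein lipase gene Lpl was 3.83-fold lower. Chemokines and cytokines were lower in 9 of 11 (-3.39, -3.89 to -2.91), with Ccl11 72.1-fold lower and Cxcl14, a marker of the class, 3.69-fold higher. Pdgfra was 3.55-fold higher (log2 1.83, 1.75 to 1.91), the growth factor receptor gene Fgfr4 20.8-fold higher and Igfbp5 75.8-fold lower, with a growth factor median of 0.28.

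The other matrix and signalling lists of this class had smaller medians with members on both sides. Among provisional matrix genes (median 0.09) the tenascin gene Tnc and Fn1 were higher, Fn1 by 4.63-fold, and Lum was 34.3-fold lower. Among fibrillar and associated collagens (-0.21, -0.36 to -0.16) Col6a3 was 2.0-fold higher and Col14a1 9.42-fold lower. Lox and Plod2 were 3.35-fold and 2.60-fold higher among collagen processing genes (0.21). Contractile genes had a median of -0.47 (-0.70 to -0.35), although the myosin kinase gene Mylk was 2.49-fold higher, and TGF-beta response genes of -0.27, with Ctgf 3.40-fold higher and Inhba 9.15-fold lower. The leading gene Wnt2 was 18.7-fold higher and Rspo1 13.5-fold lower (Wnt median -0.02). Tcf21, a marker of the class, was 6.45-fold and Snai2 3.41-fold higher, and Gata6 was 24.6-fold lower (transcription factor median -0.15). Aldh1a1, which encodes an enzyme of retinoic acid synthesis, was 5.31-fold higher and Rbp4 12.99-fold lower (retinoid median 0.17), and Hhip was 31.1-fold lower (hedgehog median -0.77). Medians were -0.33 for matrix proteases, -0.27 for complement, -0.49 for immediate early genes, 0.34 for mitochondrially encoded genes, 0.31 for proliferation, 0.12 for interferon response, -0.16 for antigen presentation, -0.13 for hypoxia and glycolysis, 0.13 for secretory genes and -0.52 for sex-linked genes. Within suffixes 1 and 4 the lipid handling median was 1.1 and 0.89 and the chemokine median -1.55 and -2.91. The immediate early median was -1.36 in 1 of these suffixes and -0.54 in the other. In suffix 1 the class held 57 cells and 114825 UMIs, and genes with under 3 UMIs entered at 3 UMIs. This can make the chemokine median less negative there. The interferon, Wnt, transcription factor, hedgehog, retinoid, secretory and sex-linked medians changed sign in a suffix.

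Col14a1-like fibroblasts carried more complement, protease and chemokine transcripts than other mesenchymal cells. Complement genes were higher in 8 of 10 with none lower (median 0.94, 0.82 to 1.01, percentile 100): Cfb was 2.45-fold and Cd55 2.23-fold higher, and C7 differed by 1.02-fold. Chemokines and cytokines were higher in 9 of 13 and lower in 2 (1.31, 0.91 to 1.69), with the eosinophil attractant gene Ccl11, a marker of the class, 15.4-fold and Ccl8 23.5-fold higher and Cxcl14 20.1-fold lower. Matrix proteases and inhibitors were higher in 7 of 13 (0.59, 0.42 to 0.78), led by Mmp3 (7.19-fold, log2 2.85, 2.73 to 2.96) and Mmp23 (3.60-fold). Contractile genes were lower in 7 of 11 with none higher (-1.23, -1.39 to -1.04), with Tagln 22.7-fold lower. Lung mesenchymal transcription factors were lower in 9 of 16 (-0.86), with Tbx2 4.98-fold lower, while Prrx1 and Klf4 were 3.01-fold and 2.65-fold higher.

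Fibrillar and associated collagens in this class had a median of 0.17 (0.03 to 0.39), with Col14a1, its own marker, 4.84-fold and Col1a2 2.79-fold higher and Col12a1 9.18-fold lower. This median was -0.03 with a lower minimum for measured genes. The secreted Wnt antagonist gene Sfrp4 was 30.7-fold higher and Wnt2 13.2-fold lower (Wnt median 0.28), and Aldh1a3 was 15.9-fold higher and Aldh1a1 3.34-fold lower (retinoid median 0.37). Growth factor genes were lower in 11 of 20 (-0.69), with Bmp5 5.40-fold lower and Figf 2.01-fold higher. Fbln2 was 4.37-fold higher and Thbs1 10.95-fold lower among provisional matrix genes (-0.02), Npnt was 39.0-fold lower among basement membrane genes (0.06), and Bmp1 was 2.98-fold higher among collagen processing genes (0.20). Medians were -0.45 for TGF-beta response (Ltbp2 7.47-fold lower), -0.71 for lipid handling, -0.60 for proliferation (Stmn1 4.95-fold lower), -0.41 for interferon response, 0.03 for antigen presentation, 0.17 for the hedgehog pathway, -0.09 for hypoxia and glycolysis, 0.21 for secretory genes, 0.15 for immediate early genes, -0.22 for mitochondrially encoded genes and -0.33 for sex-linked genes. Within suffixes 1 and 4 the complement median was 1.40 and 0.92, but the chemokine median was 0.20 (-0.24 to 0.85) and 1.00 (0.80 to 1.26). It was 0.69 at resolution 1.5 and 2.61 with the measured minimum at 100 CPM. The provisional matrix, basement membrane, antigen presentation, hedgehog and hypoxia medians changed sign in a suffix. Set directly against Col13a1-like cells, Col14a1-like cells had a chemokine median of 4.11 (3.77 to 4.51) and a complement median of 1.17 (0.87 to 1.32). Their protease median was 0.73 and their lipid handling median -1.18. The chemokine median was 0.42 and 3.26 within suffixes 1 and 4. In suffix 1 the Col13a1 class held 57 cells and 114825 UMIs. Chemokines with under 3 UMIs there entered at 3 UMIs, which can make this median smaller than the pooled one.

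Pericyte-like cells, the mural cells of small vessels, had the highest contractile transcript levels of the named classes. All 15 measured contractile genes were higher than in other mesenchymal cells (median 3.16, 2.97 to 3.56, percentile 100; 3.38 within suffix 4). The smooth muscle myosin gene Myh11 was 70.1-fold higher (log2 6.13, 5.68 to 6.57) and Mylk 1.95-fold higher. The calponin gene Cnn1 had 11 UMIs in these cells and 2 in all other mesenchymal cells (log2 ratio interval 6.74 to 12.15). Pdgfrb, a marker of the class, was 19.0-fold higher (log2 4.25, 4.01 to 4.49; 4.84 without suffix 4), Acta2 25.8-fold higher (log2 4.69, 4.50 to 4.87) and Pdgfra, with 0 UMIs, lower by a log2 of 4.01 or more. Basement membrane genes were higher in 7 of 14 and lower in 2 (0.72, 0.40 to 1.04, percentile 99.5), with the collagen IV gene Col4a1 5.19-fold higher, Lama5 6.20-fold higher from 3 UMIs (log2 2.63, 0.30 to 4.28) and Npnt 2.45-fold lower. Against ductal myofibroblast-like cells alone, 15 of 16 contractile genes were higher (1.79, 1.57 to 2.12) and 10 of 13 basement membrane genes were higher (2.77, 1.98 to 3.01).

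Fibrillar and associated collagens were lower in 7 of 13 in pericyte-like cells (median -0.59, -0.92 to -0.21), with Col14a1 4.57-fold lower and the short-chain collagen gene Col8a1 250-fold higher (log2 7.97, 7.12 to 8.89). Provisional matrix genes had a median of -0.46, with Fn1 5.24-fold lower, while Postn and the leading gene Spp1 were 174-fold and 124-fold higher. Ltbp2, a gene of a latent TGF-beta binding protein family, was 23.1-fold higher and Pmepa1, with 3 UMIs, 11.9-fold lower (log2 -3.58, -5.85 to -2.03) in the TGF-beta response list (median 0.07). The Wnt effector gene Lef1 had 12 UMIs in these cells and 1 in the others (log2 ratio interval 7.30 to 15.48; Wnt median 0.17). Tbx5 and Tbx2 were 5.54-fold and 4.29-fold higher (transcription factor median 0.09), and Pdgfa was 5.98-fold higher and Igfbp3 20.04-fold lower (growth factor median -0.79). Complement genes were lower in 8 of 9 (-1.21), matrix proteases in 8 of 13 (-0.85; Mmp2 7.77-fold lower), retinoid genes in 5 of 7 (-2.06) and chemokines in 6 of 10 (-0.78), with Cxcl12 7.93-fold lower and Tslp 4.90-fold higher. Loxl2 was 3.85-fold higher and Pcolce2 6.26-fold lower among collagen processing genes (-0.15), and the pericyte markers Higd1b and Ndufa4l2 were 1393-fold and 55.0-fold higher within the hypoxia list (0.62). Medians were 0.61 for lipid handling, 1.35 (0.61 to 1.65) for proliferation with 5 genes measured, -0.70 for the hedgehog pathway, -0.48 for secretory genes, -0.67 for immediate early genes, 0.13 for mitochondrially encoded genes and -0.26 for antigen presentation, and 2 of 7 interferon response genes were higher and 1 lower (median -0.0010, -0.50 to 0.37). The interferon, antigen presentation and Wnt medians changed sign within suffix 4. The class holds 60 cells and 106899 UMIs in all, so low levels in it rest on few UMIs. A gene low in the other cells counts as measured only where it reaches 20 CPM in this class. That choice can raise the median of a list of low genes such as proliferation, whose marker Mki67 had 1 UMI in the class. A gene with under 3 UMIs in the class entered its list median at 3 UMIs, which lies above 20 CPM here. This can also raise a median.

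**Figure D3:**
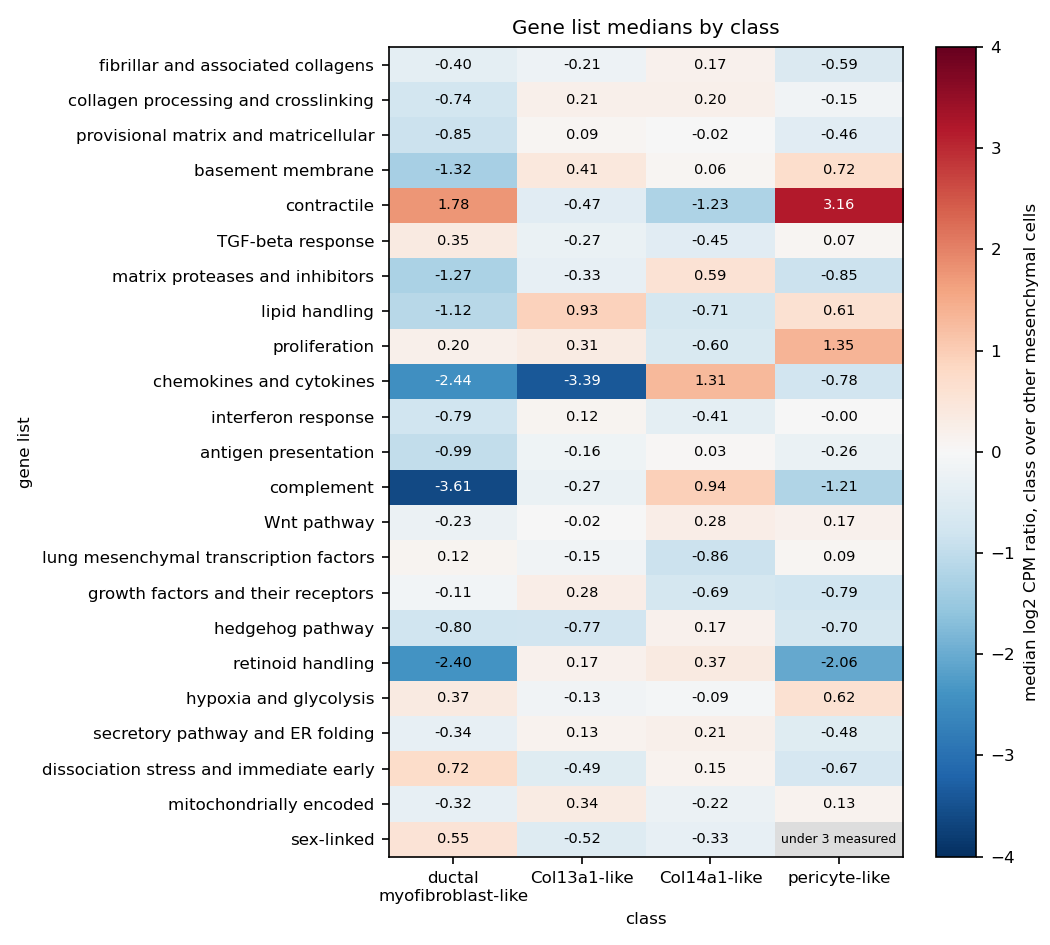
Median log2 CPM ratio of each gene list (class over other mesenchymal cells, color scale from -4 to 4) in 4 named classes. Contractile genes had medians of 1.78 and 3.16 in ductal myofibroblast-like and pericyte-like cells, and complement genes ranged from -3.61 in ductal myofibroblast-like to 0.94 in Col14a1-like cells.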

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

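The tests of the immune-like majority, and the doublet tests of cluster M4 and of the pericyte-like cells, were chosen only after the result was seen; the tests of M4 by depth and suffix and of a mixture in the pericyte-like cluster were written before, and the range over seeds was added to the M4 tests after values from a single seed had been seen.

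Hemoglobin transcripts, which no comparison used, made up 22.8% of the UMIs in the 416 barcodes that failed the cell filter and 0.0664% in the cells used, and 41 of the failing barcodes had more UMIs from hemoglobin genes than from all other genes together. Y-linked genes, also outside every comparison of suffixes, were at 323, 301 and 311 CPM over all cells of suffixes 1, 2 and 3. The X-inactivation transcript Xist was at 1919, 1553 and 1466 CPM in suffixes 4, 5 and 6. No day or gate was assigned from these values. Cluster M6 held the cardiac muscle gene Tnnt2 at 355 CPM, from 171 UMIs that all came from 1 cell, and 19837 of its 19844 UMIs of the club cell gene Scgb1a1 came from 2 cells.

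Immune-like cells made up 59.7% of a table whose labels describe a sort against CD45. The summed collagen level (Col1a1, Col1a2 and Col3a1) of immune-like cells was 24.3 CPM against 4771 CPM in mesenchymal cells, a ratio of 0.508% (0.465 to 0.555). Of immune-like cells 0.372% (0.233 to 0.563) held 3 or more collagen UMIs, compared with 91.0% of mesenchymal cells. Cells with the immune-like name thus held little mesenchymal RNA. These values argue against free immune RNA in droplets of mesenchymal cells as the source of the cells named immune-like. They argue in the same way against doublets of an immune and a mesenchymal cell as the source of most of them. A cluster took the name whose list had the highest share of passing markers, so droplets with both RNAs could have been named mesenchymal. The values cannot decide on such droplets among the cells named mesenchymal. Immune cells that passed the sort may account for the share, and no value here tests that. No biological explanation was tested, since no cell is tied to a day or gate.

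Cluster M4 took no name, with 2 Col13a1 class markers among its leading genes. Doublets of Col13a1-like and Col14a1-like cells are argued against as the source of the whole cluster by a median UMI count at 0.603 (0.552 to 0.661) of the sum of the medians of these classes, but M4 had a median doublet score of 0.0444 against 0.0275 in both classes and a median of 3429 UMIs against 2503 and 3185, so doublets among its cells stay open. Depth and suffix remain open: the best overlap with M4 (Jaccard index over 5 seeds) had a median of 0.515 (0.505 to 0.580) with cells thinned to 1500 UMIs and 0.498 (0.393 to 0.662) with genes centred per suffix. The bound of 0.5 written before does not decide either, because other seeds alone, with nothing else changed, gave overlaps from 0.492 to 0.979. No biological explanation was tested for M4.

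Pericyte-like cells had the highest contractile transcripts, and the cluster may mix pericytes with vascular smooth muscle cells. Of its 45 cells with 2 or more contractile UMIs, 38 also held a UMI of a pericyte gene (84.4%, 70.5 to 93.5). This leaves a mixture open, because the interval reaches below the bound of 80 set before and because the same pericyte genes were found in 65.0% (60.3 to 69.5) of 431 such ductal myofibroblast-like cells, whose median UMI count was 2281 against 1707.5. Doublets with another cell are argued against as the source of the whole cluster by a median UMI count at 0.620 (0.575 to 0.705) of that of other mesenchymal cells, but its median doublet score of 0.0518 was the highest of the named classes, so doublets among its cells stay open. No biological explanation was tested.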

How the results depend on the processing

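Values under alternatives added after seeing the data (leaving out a suffix, centring per suffix, another seed, equal class weights, leaving out M6 and M10) were chosen only after the result was seen. The settings meant for days and gates, and centring within a day, were not run because no cell is tied to a labelled sample. No paired analysis was possible because the columns carry no replicate numbers that would pair days or gates. Classes were set against other cells within suffixes 1 and 4 as well, with ductal contractile medians of 1.68 and 1.81. Of 268 values under 20 settings, 188 stayed within the interval of the reported value, 79 lay outside it and 1 changed sign; 72 of these were ratios of single genes, 25 of them outside. The 4 named fibroblast and mural classes were found in all 12 new clusterings. The cause of a shift was not tested unless stated. List medians followed over the settings were contractile and basement membrane for the ductal class and contractile for the pericyte-like class. For the Col14a1 class they were chemokines, complement and fibrillar collagens. No list median of the Col13a1 class was followed.

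With all barcodes kept, mesenchymal cells were 28.8% and the ductal contractile median was 1.97. At 1000 genes and 5% mitochondrial UMIs, immune-like cells were 57.2%, mesenchymal cells 32.7%, Col13a1-like cells 20.04% and pericyte-like cells 1.14%, and the ductal contractile median was 2.33. The Col13a1 share was 30.9% with doublets kept, 30.8% at resolution 1.5, 31.6% with 15 components of 1000 genes, 24.0% on the authors' normalized table, 25.7% at 1500 UMIs per cell, 33.7% centred per suffix and 32.9% with another seed. The Col14a1 share was 24.98% at resolution 0.4, 16.1% at resolution 1.5, 16.1% with 15 components, where immune-like cells were 58.2%, and 16.0% on the normalized table. At resolution 1.5 the Col14a1 chemokine median was 0.69. Thinning to 1500 UMIs, which left out 1726 cells and kept 8179, gave a ductal basement membrane median of -1.55 and a Col14a1 chemokine median of 1.83.

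Without suffix 4, immune-like and mesenchymal shares were 65.7% and 13.4%, the ductal, Col13a1, Col14a1 and pericyte shares 28.1%, 13.5%, 24.1% and 1.43%, the ductal basement membrane median -1.60, and the Col14a1 complement and fibrillar collagen medians 0.73 and 0.40. Without suffix 1, they were 63.2% and 25.5%, the ductal and Col13a1 shares 17.3% and 28.3%, the ductal contractile median 1.96 and the Col14a1 complement median 0.76. Without M6 and M10 the ductal and Col13a1 shares were 23.1% and 23.0%, by a smaller denominator.

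The mean over cells gave a ductal contractile median of 1.62 and a Col14a1 complement median of 1.11, from counts scaled here as from the authors' normalized values. A list minimum of 100 CPM gave medians of 1.32 for ductal contractile, 2.61 for Col14a1 chemokines and 0.40 for Col14a1 fibrillar collagens; a minimum of 5 CPM gave -1.68 for ductal basement membrane and -0.027 for Col14a1 fibrillar collagens, the value that changed sign, with other genes counted as measured. Equal class weights gave 0.51 for ductal contractile, 0.66 for Col14a1 complement and 0.41 for Col14a1 fibrillar collagens. TMM and DESeq2 scaling gave 1.05 and 1.05 for Col14a1 complement and 2.80 and 2.81 for pericyte contractile, by the shifts of all ratios. Depth limits what low levels show: in the pericyte-like class, with 60 cells and a median of 1707.5 UMIs, 0 UMIs of Pdgfra allow up to 34.5 CPM. The contractile median of this class was 3.05 at 1500 UMIs per cell.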

Other observations

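The values of mesothelial-like cells, of cluster M7 and of single genes below were chosen only after the result was seen.

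Mesothelial-like cells, which line the lung surface, carried more antigen presentation and interferon transcripts than other mesenchymal cells. All 10 measured antigen presentation genes were higher (median log2 ratio 1.48, 1.28 to 1.71, percentile 100), with the class I gene H2-K1 4.60-fold and the class II invariant chain gene Cd74 4.38-fold higher. Interferon response genes were higher in 5 of 9 with none lower (0.75, 0.32 to 1.19), led by Oasl2 (7.74-fold), and C2 and C3 were 5.83-fold and 4.33-fold higher among complement genes (0.49). The chemokine gene Cxcl13, which leads the cluster, was 172-fold higher, and Rspo1, a marker of the class, 18.8-fold higher. Stra6, which encodes a receptor for retinol binding protein, had 32 UMIs in these cells and 2 in other mesenchymal cells (log2 ratio interval 6.47 to 11.54). Most lists of matrix and mesenchymal regulators were lower, with medians of -1.63 for provisional matrix, -1.59 for basement membrane, -2.20 for transcription factors and -2.02 for growth factors. The basement membrane gene Nid2 was an exception at 21.7-fold higher. Without suffix 4 the cluster that matched this class best (23 cells, overlap 0.92) took no name. At 1500 UMIs per cell the best overlap was 0.641.

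The 83 cells of the unnamed cluster M7 held Pdgfra at 848 CPM. Their hedgehog and Wnt lists went both ways, with 4 of 10 hedgehog genes higher and 2 lower (median 0.30, -0.20 to 0.71) and 4 of 11 Wnt genes higher and 4 lower (0.38, -0.08 to 0.56). Among single genes, the hedgehog receptor and target gene Ptch1 was 3.45-fold higher than in other mesenchymal cells, Wnt4 5.56-fold and Dkk2 25.3-fold higher, and Cyp26b1, which encodes a retinoic acid degrading enzyme, 6.38-fold higher. Fibrillar and associated collagens were higher in 4 of 12 with none lower (median 0.43, 0.29 to 0.58, percentile 99.99), Ltbp2 was 4.72-fold higher and Igfbp5 50.6-fold lower. This cluster recurred over 4 other seeds with an overlap of 0.909 to 1, but the best overlap without suffix 4 was 0.0444.

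Immune-like cells made up 59.7% of all cells, and their share of all UMIs is not given here. Genes often used to mark lipofibroblasts had most of their UMIs in immune-like cells: 88.4% for Lpl, 90.4% for Fabp4, 83.4% for Plin2, 88.9% for Pparg and 81.2% for Fabp5. The same held for Spp1, with 87.0% of UMIs in immune-like and 4.04% in pericyte-like cells, while 44.4% of the UMIs of Postn were in the 60 pericyte-like cells. Cthrc1, a gene on the fibrotic fibroblast marker list, had 49 UMIs in all cells, of which 13 were in mesenchymal and 23 in endothelial-like cells, and no cluster took the fibrotic fibroblast name.

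Cells with UMIs of Xist and none of a Y-linked gene numbered 3, 1, 2, 2879, 1426 and 598 in suffixes 1 to 6, of 1320, 1980, 1372, 2976, 1574 and 683 cells. Cells with UMIs of a Y-linked gene and none of Xist numbered 629, 913, 804, 1, 2 and 0, and cells with both 0, 0, 1, 0, 1 and 0.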
